A study of Homo sapiens with 12 samples.

How the data were processed

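RNA of fluorescence-sorted xenograft cells was profiled on 12 Affymetrix human arrays, 3 for each combination of cell line (BT20 or HCC1806) and graft site (mammary fat pad or milk duct). The deposited values are log2 expression levels per probe set that the authors made with RMA, per the submitters' processing notes and the series text, and RMA corrects background, sets all arrays to the same quantiles and summarises the probes of each probe set. That the scale is log2 was read from the values, which run from 1.82 to 14.3 with medians of 5.58 to 5.64 on every array. Quantile normalization makes the distributions alike, so that a shift shared by most genes cannot be seen in these values. The annotation version, probe file and RMA version are not given in the sources used here. Per the labels, only RNA with an integrity number above 7 was used. The sources differ in 3 details. The series text gives 300 ng of RNA input and a sort on GFP, whereas the sample labels give 100 ng and a sort on DsRed. The series text names a smaller human array of the same maker, whereas the table holds 54675 probe sets, the set of the larger U133 Plus 2.0 array.

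Of the 54675 probe sets, 62 array controls were left out of the tests and kept for quality checks. The platform annotation paired 41097 probe sets with exactly 1 gene symbol and 1801 with several, and 11777 were unnamed here. Of the single-symbol probe sets, 41043 had an Entrez identifier in the RefSeq gene table (GRCh38.p14, used for names), which changed 0 symbols. Genes were named only from probe sets with 1 symbol, through the probe set with the highest mean over all arrays, for 19775 genes. No value was missing, and the pair of arrays with the most identical values shared 0.368% of them, so all 12 arrays were counted as separate samples.

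The computations used R 4.3.3 and limma 3.58.1. A single linear model with 1 mean per group was fitted to all 12 arrays (lmFit, contrasts.fit and eBayes, 8 residual degrees of freedom), with contrasts for the site in each line, the difference of the site effects, and the lines over both sites. P-values were adjusted by Benjamini-Hochberg within each contrast. A probe set or gene counted as changed at an adjusted p of at most 0.05 and a change of at least 2-fold, the threshold named in the series text. All p-values from limma are two-sided. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 31 lists, and again with an estimated correlation and with fry. The lists cover epithelial identity, signalling responses, stress, metabolism, proliferation and markers of other cell types, and 761 of their 831 genes were measured. The hosts were mice and the arrays human, so the lists of other cell types were not read as amounts of host cells.

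The groups, the tests, the lists, the rule for named genes and the main alternatives were fixed before the data were examined. The rule took the 10 largest rises and 10 largest falls past the threshold in each site contrast and in the line contrast, 5 each way for the difference, and 14 genes in every contrast. Where no gene passed, the 5 with the largest moderated t each way were named as not past the threshold. Of the 14 genes, 13 were measured, and TP63 is not analysed here. The scripts were tested on simulated data and on the real arrays with known changes added to 200 probe sets. These were drawn at random, and each was shifted by the same amount on every array of the changed group or line.

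Replicate numbers are shared between the groups. The alternatives were quantile normalization again, centring on the array median, only probe sets above the median of the mean levels, array weights, a trended prior, other thresholds, a replicate block, each line fitted alone, the mean of all probe sets of a gene, and each array left out in turn. Chosen after the data had been seen were the fit without intraductal replicate 2 of each line, the mean site effect of both lines, and a correlation of 2 lists without their shared genes. The 3' minus 5' signals of GAPDH and ACTB and the interquartile range of each array were compared between sites by exact permutation tests, and the 3' minus 5' signals and 2 spike-in controls were correlated with the second principal component.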

Results

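Gene expression was measured on Affymetrix human arrays in RNA from 12 samples of xenografted human breast cancer cells. BT20 and HCC1806 are established basal-type breast cancer cell lines. Cells of each line were grafted into female SCID Beige mice, an immunodeficient strain, either into the mammary fat pad or through the nipple into the milk ducts. Each line and site had 3 arrays, which gave 4 groups. The fat pad received 500000 cells and the ducts 200000, so that site and cell number changed together in every comparison of the sites. The grafted cells were sorted by their fluorescent marker before RNA extraction. Values are log2 expression levels of 54613 probe sets, which cover 19775 genes by symbol, and differences are given on the log2 scale with their standard error (SE). The number of arrays limits the precision. The labels do not say how the 3 samples of a group were kept separate beyond their numbers, so p-values measure the spread between these samples.

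The keratin and receptor levels of the 4 groups were close to each other. KRT5 and KRT14, keratins of basal epithelium, had mean levels of 12.57 and 13.13 in BT20 fat pad grafts and 12.71 and 13.26 in HCC1806 fat pad grafts. ESR1, the oestrogen receptor gene, had a mean of 6.53 in BT20 fat pad grafts and 6.67 in HCC1806 fat pad grafts, while PGR, the progesterone receptor gene, had 3.50 and 3.78. Arrays of the same group correlated with r between 0.990 and 0.997 across probe sets. Arrays of different labelled lines correlated with r between 0.983 and 0.992. The labelled line separated the arrays along the first principal component, which held 41.9% of the variance. The second component held 17.2% and set intraductal replicate 2 apart in each line, at scores of -40.4 for BT20 and -32.9 for HCC1806, against -4.02 to 26.1 for the other 10 arrays. The 3' minus 5' signal of the GAPDH control, a measure of RNA integrity, averaged 0.26 ± 0.26 (SD, n = 3) in BT20 intraductal and 0.19 ± 0.05 in BT20 fat pad arrays. It averaged 0.05 ± 0.10 in HCC1806 intraductal and 0.07 ± 0.07 in HCC1806 fat pad arrays. The exact permutation p was 0.9 in BT20 and 0.7 in HCC1806 (two-sided), where the smallest p that 3 against 3 arrays allow is 0.1. These group means hide a single array with a strong 3' bias, BT20 intraductal replicate 3. Its GAPDH signal was 0.55, against at most 0.22 on any other array, and its ACTB signal 1.91, against at most 1.46.

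**Figure D1:**
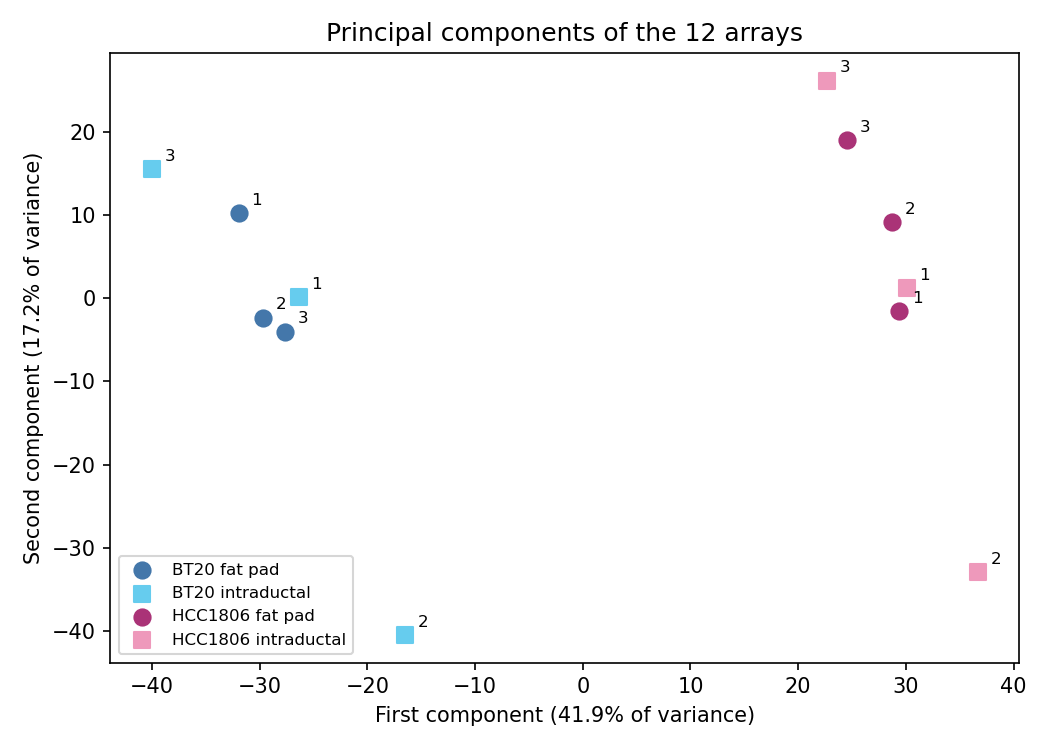
Scores of the 12 arrays on the first (41.9% of variance) and second (17.2%) principal components of the log2 values, which have no unit. Circles are fat pad and squares intraductal grafts, with the replicate number beside each. The labelled lines lie on opposite sides of the first component, and intraductal replicate 2 of each line lies lowest on the second.

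The first comparison asked whether cells grafted into the milk duct differ in expression from cells grafted into the fat pad, in BT20. No gene passed the threshold. The luminal and hormone receptor genes showed differences near 0, with ESR1 at 0.02 ± 0.15 (SE, n = 3 per site), PGR at 0.00 ± 0.10, GATA3, a luminal transcription factor, at 0.03 ± 0.09 and FOXA1, which opens chromatin for the oestrogen receptor, at -0.12 ± 0.20. PGR lay low, at a mean of 3.50 at both sites and of 3.78 and 3.92 in HCC1806, under the median level of all probe sets, 5.599. Its small differences are therefore weak evidence of no change. The luminal keratins KRT8 and KRT18 had differences of -0.27 ± 0.15 and -0.19 ± 0.13, and the basal keratins KRT5 and KRT14 had 0.01 ± 0.07 and 0.10 ± 0.08. SNAI2, a transcription factor of basal cells, stood at 0.09 ± 0.11, VIM (vimentin) at -0.12 ± 0.26, CDH1 (E-cadherin) at 0.06 ± 0.08, EGFR at 0.04 ± 0.11 and the proliferation marker MKI67 at -0.08 ± 0.13. The genes with the largest moderated t upward were CSTL1, MIR570HG, CT75, OPCML and ST8SIA4, with differences of 0.33 to 0.47, and downward RCC1, IPO9-AS1, DLC1, LINC00824 and TAF1L, with differences of -0.48 to -0.32. None of these 10 passed the threshold, with limma adjusted p = 0.9998 for each. By limma, 0 of 54613 probe sets passed an adjusted p of 0.05 with a 2-fold change, and 0 passed without the fold limit. At an unadjusted p under 0.05 there were 1283, or 2.35%, against 2730.65 that chance would give on average. The lower count is not further evidence of no site effect, since genes are correlated and such counts then vary widely. Its cause was not tested. Known 2.5-fold changes added to 200 probe sets of these arrays were recovered for 96.5% of them, and 1.5-fold changes for 46% by adjusted p alone. These probe sets were drawn at random and shifted by the same amount on each BT20 intraductal array. The recovery therefore does not cover changes that vary between grafts, or genes with a larger spread than most. It also holds for 200 changed probe sets at once. The Benjamini-Hochberg limit is stricter when only a few change, so the recovery of a few changes may be lower.

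Of the 31 gene lists, 5 shifted in BT20 by camera with a preset inter-gene correlation, and none with an estimated correlation. Genes of squamous differentiation, which build the cornified layer of stratified epithelia, shifted upward, with 33 of 41 measured genes higher in the ducts and a median difference of 0.20 (adjusted p = 3.24e-06, but adjusted p = 0.886 with an estimated correlation). Genes of NF-kB and inflammatory cytokines shifted downward, with 30 of 34 lower and a median of -0.15 (adjusted p = 0.00129, but adjusted p = 0.886 with an estimated correlation). Proliferation genes, with 34 of 42 lower and a median of -0.07 (adjusted p = 0.00129), and immediate early genes, with 20 of 27 lower and a median of -0.06 (adjusted p = 0.00553), shifted downward too, but each had an adjusted p = 0.886 with an estimated correlation. The fibroblast markers shifted downward as well, with 20 of 25 lower and a median of -0.07 (adjusted p = 0.00553, but adjusted p = 0.298 with an estimated correlation). Stromal cells of the grafts come from the mouse host and the arrays are human, so this shift is not read as a change in stromal cells. No single member of these lists passed the test over all genes. Members with large differences, chosen after their values were seen, were the cornified envelope genes SPRR1B at 0.92 ± 0.46 and SPRR1A at 0.86 ± 0.46, the neutrophil chemokines CXCL3 at -0.73 ± 0.25 and CXCL2 at -0.71 ± 0.26, and the collagen gene COL1A2 at -0.53 ± 0.15. SPRR1B and SPRR1A stood at 7.95 and 8.43 in fat pad replicate 1. In fat pad replicates 2 and 3 they stood at 9.65 and 9.67, and at 9.78 and 9.93, so both differences rest largely on replicate 1. S100A8 and S100A9, alarmin genes that stand in both the squamous and the inflammatory list, had differences of 0.76 ± 0.48 and 0.73 ± 0.46. S100A8 stood at 10.02 in fat pad replicate 1, against 12.29 and 11.98 in fat pad replicates 2 and 3, so its difference rests largely on that array. Adjusted over the list alone, 1 gene of any list passed, DLC1 of the YAP and TEAD response list, which lies at -0.43 ± 0.10 (adjusted p = 0.0219 over that list), against 0 over all genes. With single BT20 arrays left out, the squamous call ended without fat pad replicate 1 (adjusted p = 0.575, median 0.06) or intraductal replicate 3 (0.181, median 0.08), and the proliferation call without intraductal replicate 1 (0.139). The inflammatory call ended without intraductal replicate 2 (0.871), where the median went from -0.15 to -0.05, or without replicate 1 (0.115) or fat pad replicate 2 (0.0968) or 3 (0.0595). The immediate early call ended without intraductal replicate 2 (0.368) or 1 (0.139) or fat pad replicate 3 (0.177), and the fibroblast call without intraductal replicate 3 (0.160) or 1 (0.115) or fat pad replicate 1 (0.0568). Intraductal replicate 3, without which the squamous and fibroblast calls ended, had the strongest 3' bias of all arrays. The squamous list also had its highest mean level there, 8.17. An effect of RNA quality on these calls was not tested. The other 26 lists did not pass, among them luminal epithelial genes, whose median was 0.02 with 17 of 29 genes higher while their mean was -0.03 and camera pointed downward (adjusted p = 0.886), and estrogen response genes, with 12 of 23 higher and an adjusted p of 0.557. By fry the lowest adjusted p of any list was 0.657.

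The same comparison in HCC1806 also gave no gene past the threshold. VIM, an intermediate filament gene of mesenchymal cells, had the largest difference among the genes fixed beforehand, at -0.53 ± 0.26 (SE, n = 3 per site), whereas its other probe set stood at 0.08. EGFR stood at 0.24 ± 0.11, KRT14 at 0.19 ± 0.08, SNAI2 at 0.17 ± 0.11, KRT5 at 0.10 ± 0.07 and CDH1 at 0.04 ± 0.08. The luminal genes KRT8, KRT18, GATA3 and FOXA1 had differences of -0.21 ± 0.15, -0.15 ± 0.13, -0.05 ± 0.09 and -0.07 ± 0.20. ESR1 stood at -0.03 ± 0.15, PGR at 0.14 ± 0.10 and MKI67 at -0.08 ± 0.13. The genes with the largest moderated t upward were CHIC1, PFAS, PITPNC1, IL1RAPL1 and LINC01282, with differences of 0.29 to 0.74, and downward LINC01963, ADGRE3, LIMCH1, BDKRB1 and CCL26, with differences of -0.53 to -0.34. None passed the threshold (limma adjusted p = 0.9999 for each). By limma, 0 of 54613 probe sets passed with the 2-fold limit and 0 without it, with 1743, or 3.19%, at an unadjusted p under 0.05. Without HCC1806 intraductal replicate 3, 3 probe sets passed, those of CXCL14, SLC35D3 and PITPNC1, with differences of 2.14, 1.43 and 1.05. With all arrays their differences were 1.39, 0.90 and 0.74. Changes of 2.5-fold added to 200 probe sets were recovered for 98.5% of them, with the same limits as in BT20.

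In HCC1806, 13 lists shifted by camera with the preset correlation, and none with an estimated correlation. The list of NF-kB and inflammatory cytokines had 29 of 34 genes lower and a median difference of -0.24 (adjusted p = 1.52e-05, but adjusted p = 0.526 with an estimated correlation). Cholesterol synthesis had 17 of 19 genes lower with a median of -0.10 (adjusted p = 0.000779), and heat shock proteins 16 of 18 with a median of -0.10 (adjusted p = 0.00119), but each had an adjusted p = 0.526 with an estimated correlation. Genes of epithelial-mesenchymal transition had 26 of 35 lower with a median of -0.08 (adjusted p = 0.00713) and extracellular proteases 16 of 20 with a median of -0.09 and a mean of -0.24 (adjusted p = 0.0125). With an estimated correlation these had adjusted p = 0.526 and 0.568. Hypoxia, glycolysis and proliferation genes and the markers of leukocytes and of erythroid cells also shifted downward, with medians of -0.05, -0.05, -0.04, -0.04 and -0.13 and adjusted p from 0.0266 to 0.0442, but adjusted p = 0.526 to 0.715 with an estimated correlation. Leukocyte, erythroid and endothelial markers had mean levels of 5.17 to 5.37 in HCC1806, under the median level of all probe sets, 5.599. Such cells come from the mouse host, so these lists are not read as measures of them. Immediate early genes, with 20 of 27 higher and a median of 0.10 (adjusted p = 0.0125), squamous differentiation genes, with 27 of 41 higher and a median of 0.06 (adjusted p = 0.0168), and basal and myoepithelial genes, with 16 of 23 higher and a median of 0.05 (adjusted p = 0.0418), shifted upward. With an estimated correlation their adjusted p = 0.526, 0.715 and 0.526. Members with large differences, chosen after their values were seen and none past the test, were the matrix metalloproteinases MMP10 at -0.998 ± 0.51, MMP13 at -0.98 ± 0.38 and MMP1 at -0.87 ± 0.57, the chemokine CXCL6 at -0.64 ± 0.36, the keratin KRT13 at 0.69 ± 0.37 and FOS at 0.57 ± 0.44. MMP10 and MMP1 stood at 6.28 and 7.86 in intraductal replicate 2. In intraductal replicates 1 and 3 they stood at 7.31 and 8.82, and at 9.53 and 10.72, so both differences rest largely on replicate 2. Adjusted over the list alone, 1 gene passed, ROBO4 of the endothelial markers, at -0.36 ± 0.10 (adjusted p = 0.0488 over that list), against 0 over all genes. Without HCC1806 intraductal replicate 2, 2 lists passed, without HCC1806 fat pad replicate 3 there were 5, and without HCC1806 fat pad replicate 1 there were 6. The inflammatory and cholesterol calls ended without intraductal replicate 2 alone (adjusted p = 0.633 and 0.0801), where their medians went to -0.0248 and -0.04, so that the size of the inflammatory shift rests largely on that array. Leaving it out also ended the calls of extracellular proteases (0.807), whose median went to -0.00112, and of epithelial-mesenchymal transition (0.295) and heat shock proteins (0.116), with medians of -0.03 and -0.05. The squamous call ended too (0.633) though its median stayed at 0.06. The proliferation median turned to 0.0187 without that array (0.319), and the hypoxia median went from -0.05 to -0.14 with its call held (6.6e-07). The heat shock call ended as well without fat pad replicate 1 (0.373), the squamous call without fat pad replicate 3 (0.705), the transition call without fat pad replicate 2 (0.145), the protease call without fat pad replicate 2 (0.231) or 3 (0.0908), and the immediate early call without fat pad replicate 2 (0.231) or intraductal replicate 1 (0.270). The basal, leukocyte, erythroid, hypoxia, proliferation and glycolysis calls held in 7, 7, 8, 4, 4 and 3 of the 12 fits with an array left out. Luminal epithelial genes did not pass, with 16 of 29 lower and a median of -0.02 (adjusted p = 0.861), nor did estrogen response genes, whose median was -0.01 and mean 0.04 (adjusted p = 0.861). By fry the lowest adjusted p of any list was 0.143.

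**Figure D2:**
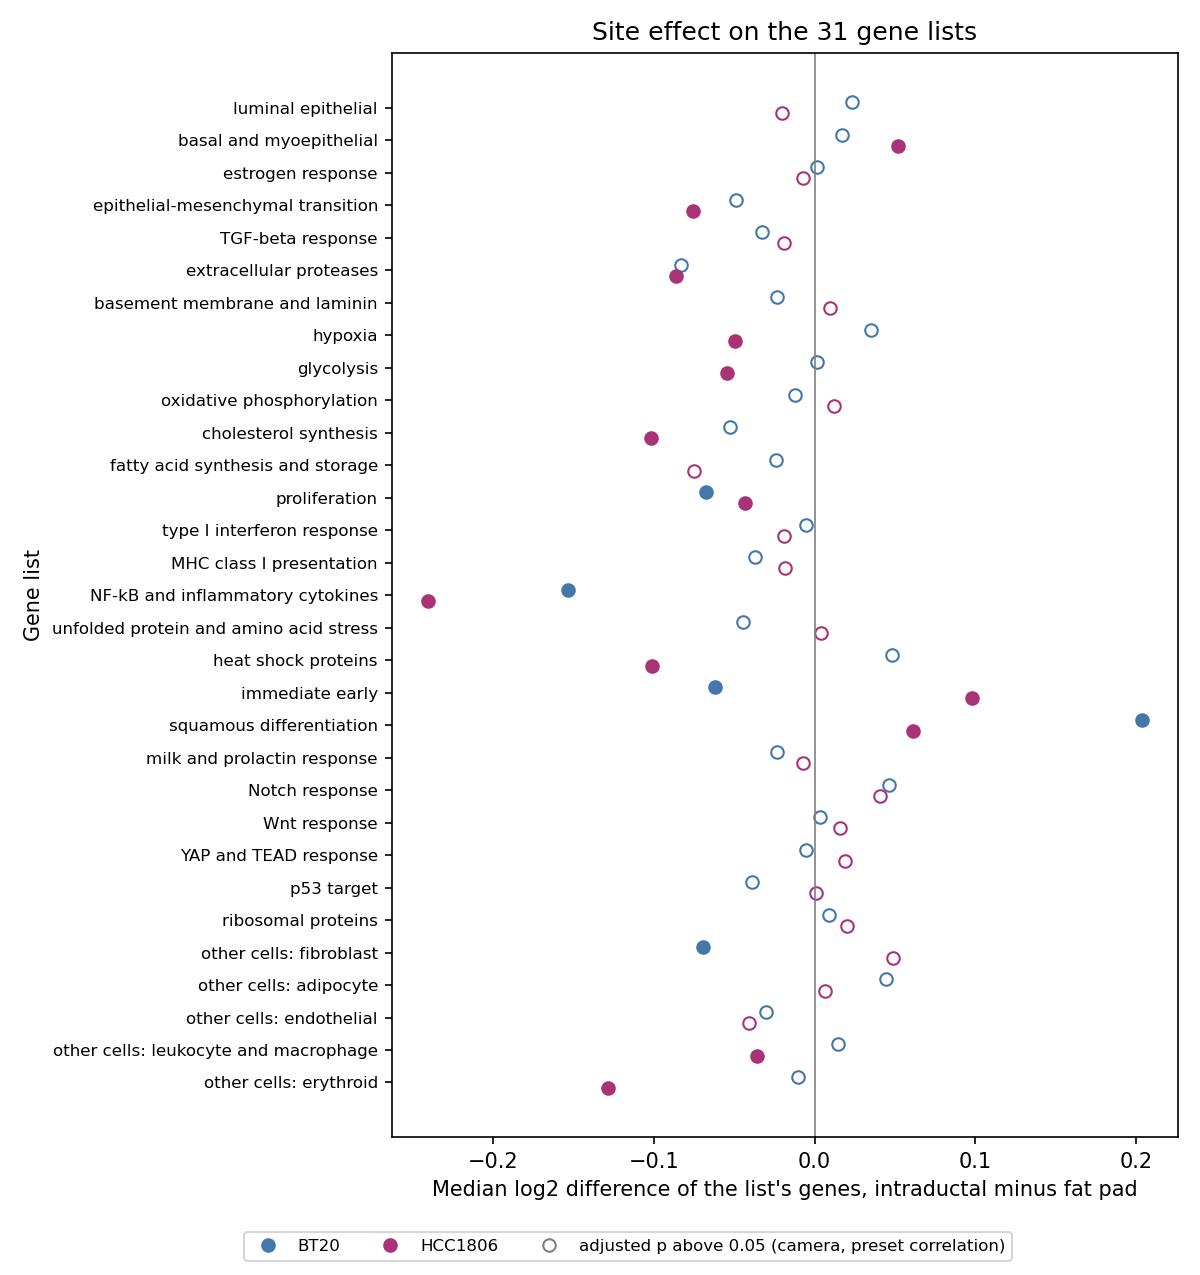
Median log2 difference (intraductal minus fat pad) of the genes of each of the 31 lists, in BT20 (blue) and HCC1806 (purple), 3 arrays per group. Filled points passed camera with the preset correlation at an adjusted p of 0.05, which 5 lists did in BT20 and 13 in HCC1806, and none passed with an estimated correlation.

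The site effect was then compared between the lines. No gene differed past the threshold in its response to the site. The genes with the largest moderated t toward a higher site effect in BT20 were ENPP2 at 0.61 ± 0.14 (SE), CSTL1 at 0.50 ± 0.13, SERTAD4 at 0.50 ± 0.13, RASSF9 at 0.42 ± 0.11 and ZNF786 at 0.54 ± 0.15. Toward a lower site effect in BT20 they were RCC1 at -0.54 ± 0.14, PFAS at -0.41 ± 0.11, NHSL2 at -0.45 ± 0.12, FHL1P1 at -0.42 ± 0.12 and TBX22 at -0.36 ± 0.10. All 10 had a limma adjusted p of 0.999. ESR1, PGR, GATA3, FOXA1, KRT8, KRT18, KRT5, KRT14, SNAI2, CDH1, EGFR and MKI67 had differences between -0.20 and 0.07, and VIM had 0.41 ± 0.37. By limma, 0 of 54613 probe sets passed with the 2-fold limit and 0 without it, with 1231, or 2.25%, at an unadjusted p under 0.05. Changes of 2.5-fold added to 200 probe sets, again drawn at random and shifted evenly, were recovered for 90% of them and changes of 1.5-fold for 0%, with the same limits as in the site contrasts.

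By camera with the preset correlation, 4 lists differed in their site effect between the lines. Immediate early genes, which respond within minutes to growth factors and stress, had a lower site effect in BT20 for 25 of 27 genes, with a median difference of -0.18 (adjusted p = 7.24e-05, but adjusted p = 0.573 with an estimated correlation). Heat shock protein genes had a higher site effect in BT20 for 17 of 18 genes, with a median of 0.16 (adjusted p = 0.000105, but adjusted p = 0.573 with an estimated correlation), and hypoxia genes for 20 of 29, with a median of 0.10 (adjusted p = 0.0197, but adjusted p = 0.847 with an estimated correlation). The fibroblast markers had a lower site effect in BT20 for 21 of 25 genes, with a median of -0.08 (adjusted p = 0.00343, but adjusted p = 0.200 with an estimated correlation). Among them COL3A1, COL1A2 and POSTN, chosen after their values were seen, stood at -0.98 ± 0.38, -0.67 ± 0.21 and -0.63 ± 0.19. By fry the lowest adjusted p of any list was 0.455.

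No probe set changed the same way in both lines past the threshold, since limma called 0 in each. At an unadjusted p under 0.05, 49 of the 19775 genes moved the same way in both lines, where independent lists of these sizes would share 9.39 upward and 10.9 downward. Across genes, which are not independent replicates, the site effects of the lines correlated with Pearson's r of 0.18 and Spearman's rho of 0.10, and 53.1% of genes had the same sign. The exact permutation p over all 400 relabellings of the sites within lines was 0.51. The correlation turned to -0.05 without HCC1806 intraductal replicate 2 and fell to 0.02 without BT20 intraductal replicate 2. In the mean of both lines, a contrast added after the 2 site contrasts had been seen, 0 probe sets passed and 1633 had an unadjusted p under 0.05 by limma. In that contrast 7 lists passed camera with the preset correlation, 2 upward (squamous differentiation and basal and myoepithelial genes) and 5 downward (inflammatory cytokines, proliferation, cholesterol synthesis, epithelial-mesenchymal transition and extracellular proteases), but 0 with an estimated correlation (adjusted p = 0.513 to 0.729 with an estimated correlation) and 0 by fry.

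The last comparison set the arrays labelled BT20 against those labelled HCC1806, over both sites. Of the genes, 21 were higher and 25 lower in the arrays labelled BT20 by at least 2-fold, and 0 differed by 4-fold or more, with each gene read from a single probe set. Over all probe sets, 3 without a single gene symbol passed 4-fold, at differences of 2.22, 2.16 and -2.61. The highest in BT20 were CXCL5, a neutrophil chemokine, at 1.89 ± 0.21 (SE, n = 6 arrays per line, adjusted p = 4.01e-05), CYP2R1, a vitamin D 25-hydroxylase, at 1.87 ± 0.10 (adjusted p = 5.37e-07), ROBO1, a receptor of axon guidance, at 1.74 ± 0.14 (adjusted p = 3.34e-06), and the transcription factor genes TRPS1 at 1.61 ± 0.11 and MAF at 1.504 ± 0.15. EGR3, NLGN4X, OLFM4, EDNRB and LUM followed with differences of 1.196 to 1.39. The lowest in BT20 were FBN2 (fibrillin 2) at -1.86 ± 0.16 (adjusted p = 7.04e-06), CRISPLD1 at -1.68 ± 0.15 (adjusted p = 8.87e-06), LOC105371703 at -1.61 ± 0.11, LINC01029 at -1.48 ± 0.09 and CUX2 at -1.39 ± 0.12. LINC01986, ADGRF5, LINC01419, ZIC2 and ZNF850 followed with differences of -1.37 to -1.25. Of these 20 genes, 18 lay under the median level of all probe sets, 5.599, in at least 1 line, where background limits the measured fold, so that their differences and ranks are approximate. Averaged over all probe sets of each gene, 8 of the 20 stayed under 2-fold, namely CXCL5 at 0.83, MAF at 0.30, NLGN4X at 0.98, EDNRB at 0.75, LUM at 0.69, FBN2 at -0.68, CUX2 at -0.65 and ADGRF5 at -0.72.

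**Figure D3:**
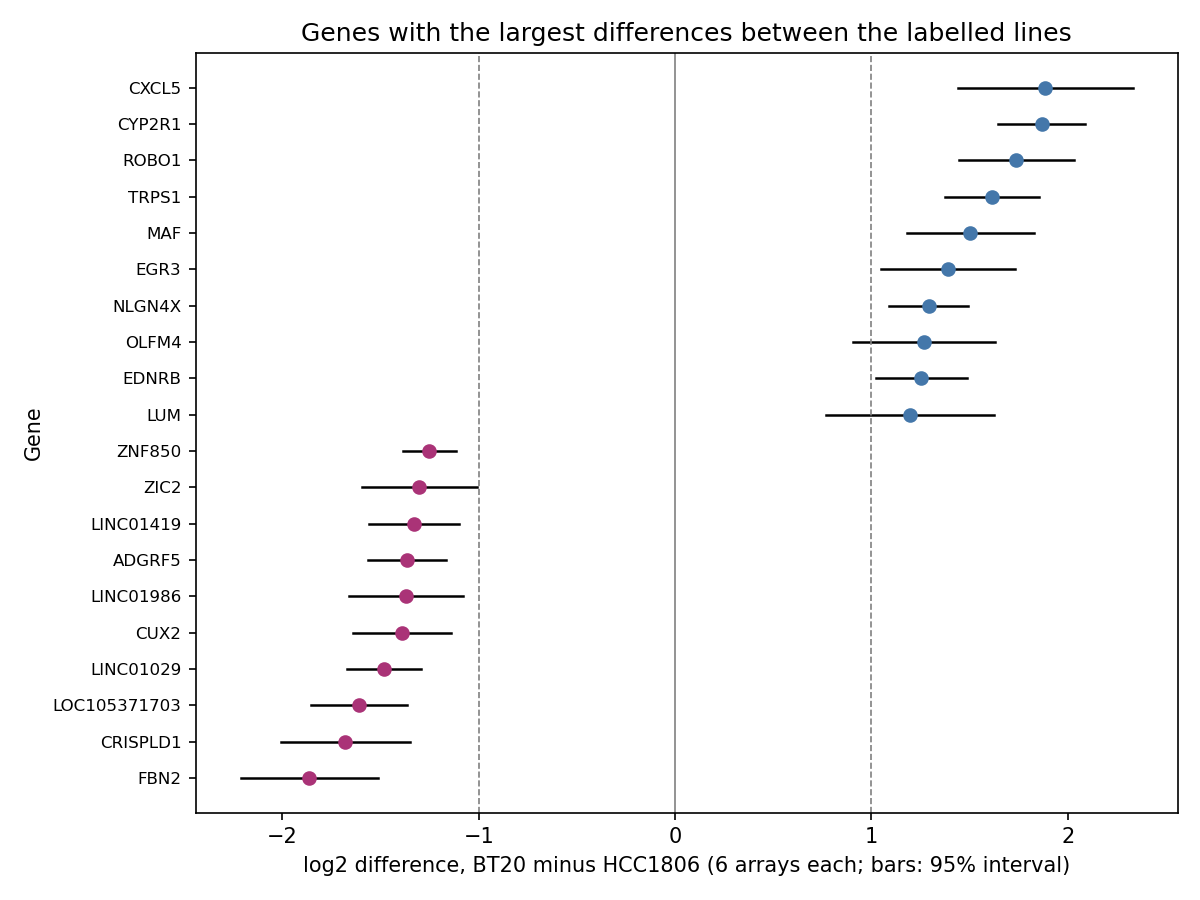
Log2 difference between arrays labelled BT20 and HCC1806 (6 arrays each) for the 20 genes named by rule, with 95% confidence intervals from limma. Dashed lines mark a 2-fold difference, and the genes range from FBN2 at -1.86 to CXCL5 at 1.89.

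EGFR, which is known to be amplified in BT20, had a mean of 10.83 ± 0.09 (SD, n = 6) in the arrays labelled BT20 and 10.86 ± 0.22 in those labelled HCC1806, a difference of -0.03 with a 95% confidence interval of -0.21 to 0.14. SNAI2, PGR, KRT5, KRT14 and GATA3 differed by -0.32, -0.35, -0.19, -0.18 and 0.18, with limma adjusted p from 0.00213 to 0.0477 over genes and all under 2-fold. PGR's other probe set differed the opposite way, at 0.27 (adjusted p = 0.0380 over probe sets), and both lie low, at mean levels of 3.11 and 3.67, so no direction is given for PGR. The GATA3 probe set had an adjusted p of 0.0534 over all probe sets. ESR1, FOXA1, KRT8, KRT18, VIM, CDH1 and MKI67 did not pass the adjusted p, with differences from -0.17 to 0.27. Other probe sets of ESR1, EGFR, VIM and MKI67 passed it over probe sets, all under 2-fold, with differences from -0.35 to 0.31 for ESR1, from -0.22 to 0.34 for EGFR, of 0.61 for VIM and of -0.22 for MKI67. Over probe sets, 120 passed the threshold by limma, 61 higher and 59 lower in BT20, and 16404, or 30.0%, passed the adjusted p without the fold limit, 6887 higher and 9517 lower in BT20. Of the 120, 74 lay under the median level of all probe sets, 5.599, in both lines, and 29 were called when only probe sets above the median of the mean levels were tested. None of the 31 lists passed camera with the preset correlation, while by fry, which asks whether a list's genes move on balance in a single direction, 8 passed. These were oxidative phosphorylation, proliferation, type I interferon response, MHC class I presentation, unfolded protein and amino acid stress, YAP and TEAD response, p53 target and endothelial marker genes, all lower in BT20 with medians of -0.17 to -0.06. Fry compares a list with no change and not with other genes, of which more were lower than higher in BT20.

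**Figure D4:**
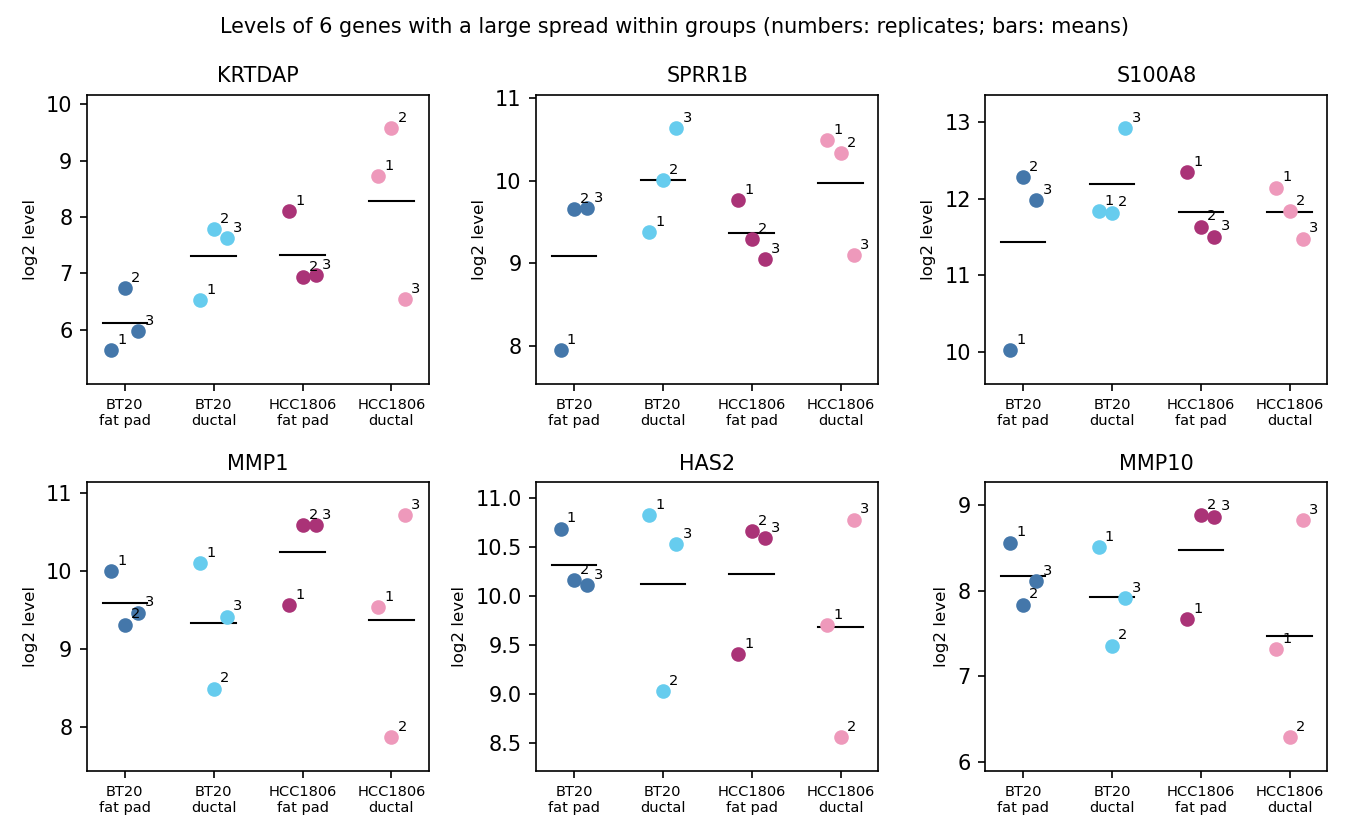
Log2 expression level of 6 genes on each of the 12 arrays, grouped by line and site, with the replicate number beside each point and the group mean as a bar. The genes were chosen after their values were seen from the 20 with the largest standard deviation within groups, and KRTDAP ranges from 5.64 to 9.57.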

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

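The tests of the near identity of the labelled lines (genes that differ 8-fold, EGFR, and the share of probe sets that differ) were chosen only after the result was seen, as were the direction of the 3' bias in intraductal replicate 2, the fit without both intraductal replicate 2 arrays and the choice of which split and which labels to examine in HCC1806.

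In 4 gene lists the site effect differed between the lines by the test of the difference itself (camera with the preset correlation). The median difference, BT20 minus HCC1806, was 0.10 for hypoxia genes, 0.16 for heat shock proteins, -0.18 for immediate early genes and -0.08005 for fibroblast markers. None of the 4 passed with an estimated correlation (adjusted p = 0.200 to 0.847) or by fry (0.455 to 0.925). The immediate early call held with each of the 12 arrays left out in turn, at a camera adjusted p of at most 0.00902. These fits kept the preset correlation, so they do not bear on the loss of the call with an estimated correlation. The mean level of that list per array differed between the sites by -0.12 in BT20 and 0.10 in HCC1806. The exact permutation p was 0.2 and 0.3, where 0.1 is the smallest that 3 against 3 arrays allow. The heat shock call ended without HCC1806 fat pad replicate 1 (adjusted p = 0.0622) and the fibroblast call without BT20 intraductal replicate 3 (0.101). The hypoxia call ended without HCC1806 intraductal replicate 1 (0.398) or 3 (0.0551), HCC1806 fat pad replicate 1 (0.103), BT20 intraductal replicate 3 (0.323) or BT20 fat pad replicate 1 (0.106). With both intraductal replicate 2 arrays left out, the hypoxia, immediate early and fibroblast calls held and the heat shock call did not (adjusted p = 0.0848). The median difference then was 0.19 for hypoxia genes and 0.08 for heat shock proteins, and glycolysis, proliferation and squamous differentiation genes passed as well (adjusted p = 0.0474, 0.00475 and 0.00475).

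Other splits of the arrays were counted for each number of calls. For the line contrast, 1 of 100 splits of the lines within sites, the labelled one, gave as many as its 120 probe sets, and the highest of the others gave 1. That is the smallest share that 100 splits can give. The other splits mix the lines, which adds the line difference to the spread within groups and lowers their counts. For the difference of the site effects all 100 splits gave at least the observed 0, with 2 as the highest other. No count can lie under 0, so this outcome was fixed beforehand and decides nothing. For each site contrast the 10 splits of 6 arrays are too few for a share under 0.05. All 10 gave at least the observed 0, again fixed beforehand, with the highest other at 0 in BT20 and 12 in HCC1806.

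The arrays of the labelled lines were nearly alike, with 0 genes that differed 8-fold or more, probe set differences of at most 2.22 upward and -2.61 downward (log2), and EGFR at -0.0346 (log2, BT20 minus HCC1806), although BT20 is known for EGFR amplification. Complete removal of line means by the authors' processing is argued against by the 30.0% of probe sets that differ at an adjusted p of 0.05, and artefacts of single probe sets, as the source of the direction, by other probe sets of the same genes at or above the median level, whose share with the same sign was 0.889 (48 of 54) and by gene 0.967 (29 of 30, 95% interval 0.828 to 0.999). Probe sets that were called themselves were left out of these 54, which fixed smaller differences among them beforehand. They therefore cannot test the size of the called differences. Their median difference in the called direction was 0.27, and by limma 27 of the 54 passed an adjusted p of 0.05 with the same sign and 2 with the opposite sign. In 5 genes 2 or more probe sets were called, and in 0 of these genes did the called probe sets differ in direction. The values are consistent with RNA of a single cell source under both line labels, as a hypothesis, with small stable differences between its 2 sets of grafts. Of all probe sets, 97.1% differed by less than 1.5-fold between the labelled lines. Under that hypothesis the site contrasts of BT20 and HCC1806 would not stand for 2 different cell lines. A partial adjustment of the line means, a batch that runs with the lines and true similarity of these xenografts stay open, since the labels give no batch and no ungrafted cells of either line were analysed here.

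Intraductal replicate 2 lay apart from the other arrays in both lines on the second principal component. The 2 arrays deviated together from their group means, with r = 0.50 across probe sets. More degraded RNA in these 2 arrays is argued against by their GAPDH 3' minus 5' signal, which lay lowest in each line and deviated from the line means by -0.149 on average (log2, one-sided exact permutation p = 0.0278 over the 36 choices of an array per line, the smallest they can give), as did that of ACTB by -0.240 (exact permutation p = 0.0278). Degradation that differs among the other arrays cannot be told apart from other causes, since the GAPDH signal correlated with the component over the 12 arrays with r = 0.46 (permutation p = 0.146, adjusted over 4 measures 0.195; rho = 0.41, permutation p = 0.193; r = 0.20 without the 2 farthest arrays) and within the lines with r = 0.73 in BT20 and 0.73 in HCC1806 (n = 6, exact permutation p = 0.174 and 0.0944). Of the other 3 measures, the poly-A spike dap, a control of labelling, had the largest r, -0.56 (permutation p = 0.0566, adjusted 0.195), with rho = -0.30 (permutation p = 0.340), r = -0.50 without the 2 farthest arrays, and r = -0.44 in BT20 and -0.80 in HCC1806 (n = 6, exact permutation p = 0.408 and 0.0403), so a difference in labelling stays open too. No biological explanation was tested, as the labels name nothing that these 2 grafts share beyond site and number.

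In HCC1806 the split that set fat pad replicate 1 with intraductal replicates 1 and 2 gave 12 probe sets, against 0 for the labelled split and each of the other 8, which points to a structure of the samples, though it was picked as the highest of 10 splits, has intraductal replicate 2 on one side, and was not tested against chance. Swapped labels of fat pad replicate 1 and intraductal replicate 3 could give it. After such a swap the HCC1806 site effect correlated with that of BT20 across genes with r = 0.24, against 0.18 as labelled, rank 4 of the 20 labellings. These 20 are 10 splits, each taken in both directions with the sign of r reversed. Every labelling with intraductal replicate 2 on the intraductal side gave a positive r, and every other a negative r. The measure thus follows that array, and the test leaves a swap undecided. With the HCC1806 mean of each gene removed, fat pad replicate 1 had a negative r with every other HCC1806 array. It was -0.23 and -0.05 with intraductal replicates 1 and 2, and -0.46 and -0.13 with fat pad replicates 2 and 3. Intraductal replicate 3 had r = -0.00643 and 0.29 with fat pad replicates 2 and 3, and -0.33 and -0.60 with intraductal replicates 1 and 2. These values leave a swap undecided too. A site-independent state of the grafts, such as their size or growth phase, stays open and was not tested.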

How the results depend on the processing

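The alternatives without intraductal replicate 2 of both lines and the mean site effect, and those of the spread within groups, were chosen after the data had been seen. Counts of changed probe sets stayed at 0 in the BT20 site contrast, the difference and the overlap of the lines under every alternative run. The HCC1806 site count ranged from 0 to 3 and that of the mean of both lines from 0 to 1 with single arrays left out, the higher value in each case without HCC1806 intraductal replicate 3. The line count was 29 among probe sets above the median of the mean levels, where fewer probe sets are tested, 16404 without the fold limit, and 107 to 146 with single arrays left out. The correlation of the site effects was -0.0478 to 0.267 with single arrays left out, and negative without HCC1806 intraductal replicate 2. The number of lists past the threshold went to 0 in the BT20, HCC1806 and difference contrasts with an estimated correlation and by fry. In the line contrast it was 8 by fry, 1 after quantile normalization (immediate early genes) and 3 without both intraductal replicate 2 arrays (oxidative phosphorylation, proliferation and immediate early genes). Without these arrays HCC1806 had 2 lists (hypoxia, whose median moved from -0.05 to -0.14, and immediate early), BT20 had 4, with type I interferon response among them (adjusted p = 0.0109), the difference had 6, and the median of HCC1806 proliferation genes turned to 0.0187, the highest of a range from -0.0885 to 0.0187 with single arrays left out. With single arrays left out the number of lists ranged from 1 to 6 in BT20, 2 to 13 in HCC1806, 3 to 10 for the difference and 0 to 2 for the lines. Of the 22 list calls of the site and difference contrasts, 19 held under the replicate block and 1 with every single array left out. Same-numbered samples did not deviate together in every pair (r from -0.30 to 0.50), which shows no consistent pairing by number and leaves the origin of the samples open. The highest r was that of the intraductal replicate 2 arrays of BT20 and HCC1806. The replicate block left the counts at 0 for each site contrast and the difference and at 120 for the lines, the site correlation at 0.18, and the lists at 5, 10, 4 and 0. For named genes, 1873 of 1882 values kept direction and side of the threshold, 8 lost the 2-fold limit with the mean of all probe sets, and 1 (PITPNC1) passed without HCC1806 intraductal replicate 3. Except where fewer probe sets or arrays explain it, the cause was not tested. Of the 120 line probe sets, 74 lie under the median level, where signal over background limits the fold.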

Other observations

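The tests of the spread of the squamous and inflammatory lists were chosen only after the spread had been seen, and so were the spread without both intraductal replicate 2 arrays and the correlation without shared genes. The spread between arrays of the same group was not even over the genes. The largest standard deviations within groups were those of HBE1, an embryonic globin gene, at 0.98 (log2, over 12 arrays with group means removed), and KRTDAP, a keratinocyte differentiation gene, at 0.96, against a median of 0.13 over all genes. Others among the 20 largest, chosen after their values were seen, were the interstitial collagenase gene MMP1 at 0.89, the antimicrobial S100A7 at 0.87, the hyaluronan synthase HAS2 at 0.83 and the cornified envelope gene SPRR1B at 0.72. MMP1 stood at 7.86 in HCC1806 intraductal replicate 2 and 10.72 in HCC1806 intraductal replicate 3. S100A8 stood at 10.02 in BT20 fat pad replicate 1 and 12.29 in BT20 fat pad replicate 2.

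The median standard deviation within groups was 0.26 for squamous differentiation genes and 0.33 for NF-kB and inflammatory cytokine genes, against medians of 0.12 and 0.12 for 10000 random lists of the same size matched on level, and above all of them (permutation p = 1e-04 for each, one-sided, the smallest these lists can give). Ribosomal protein genes had 0.06 and oxidative phosphorylation genes 0.09. In all, 10 of the 31 lists exceeded their random lists at an adjusted p of 0.05, among them immediate early genes at 0.23 and extracellular proteases at 0.21. The inflammatory list was lowest on the arrays that lay apart, with a mean level of 8.07 in BT20 intraductal replicate 2 and 7.85 in HCC1806 intraductal replicate 2, against 8.34 to 8.70 on the other 10. Without these 2 arrays its median standard deviation was 0.22 and that of the squamous list 0.22, each still above all 10000 random lists (permutation p = 1e-04, one-sided, the smallest they can give). The p-values of these standard deviations come from random draws of genes, not from relabelled arrays, and treat the genes of a list as independent. The estimated inter-gene correlation was 0.36 in the squamous and 0.46 in the inflammatory list. A few deviant arrays can then raise the standard deviation of a whole list, so these p-values may be far too small. As a hypothesis only, xenografts of 1 group may differ in a squamous and in an inflammatory state, and differences between arrays in RNA or labelling stay open. A hypothesis that both states exclude each other was not borne out by the criterion set beforehand, a negative correlation over all arrays with a permutation p of at most 0.05. With the 2 genes that stand in both lists, S100A8 and S100A9, left out, the lists correlated over the 12 arrays with group means removed with r = -0.0383 (permutation p = 0.909, rho = 0.11, permutation p = 0.778), and with r = -0.42 without the 2 farthest arrays. With these genes r was 0.16 (permutation p = 0.648). Within the lines r was 0.61 in BT20 and -0.83 in HCC1806 (n = 6 each), a difference that was not tested.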
